A study of Mus musculus with 4 samples.

How the data were processed

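RNA was measured in scraped epithelial tissue of mouse jejunum and ileum on 1-colour (Cy3) Agilent mouse arrays. Per the labels, the mice were 9 weeks old, on the C57BL/6J background, and lacked the T cell receptor beta and delta genes. They carried either the wild-type form of the gene for D-amino acid oxidase (DAO) or the G181R form on both copies. RNA of 5 mice was pooled for each of the 4 groups and hybridised to 1 array per group, from 100 ng of RNA with an integrity number over 9. There was no replicate array in any group, so no p-value and no error between animals could be computed.

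The scanner files hold intensity values that, per the file headers, Agilent Feature Extraction 11.5.1.1 made by subtracting background and removing spatial and multiplicative trends within each array, with no scaling between arrays. The same files hold other values, flags of 0 or 1 for each spot that, per the file headers, mark signal well above background, saturation and outliers. The deposited value table holds log2 values. They equal the log2 of the processed intensity minus 1 constant per array for 95.8% of the 56605 probes on every array, within a tolerance of 0.01. Nearly all of the others are 2356 probes that lie at the start of the scanner files and hold 1 identical value per array that is not their scanner value. Those probes include the brightest one for Dao and for 1582 genes in all, so the scanner intensities were used throughout and the deposited table served only as an alternative.

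The log2 processed intensity was averaged over the spots of a probe, leaving out spots marked as outliers, and the array's 75th percentile over non-control probes was subtracted. Of the 62976 spots on an array, those of 300 probes were printed 10 times each. The brightest probe over the 4 arrays stood for its gene. A gene counted as measured in a comparison when its probe was well above background on both arrays, and it was counted as different from a fold of 2. Where a probe was well above background on 1 array only, the fold is given as "at least", computed against the probe's own signal on the other array or the lowest signal well above background there, whichever was higher. Of the probes, 32994 took their gene symbol through the RefSeq accession in the GRCm38.p6 gene table, 19 from the description, and 23592 kept the name of the array design. These made 37057 names, of which 16894 were clone names, predicted models or accessions. Coordinates are probe positions in mm9, as the files give them. The chromosome of the chosen probe differed from that of the gene table for 104 of 24689 genes.

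The number of probes well above background was 32505 and 34187 in jejunum (wild-type and G181R) and 33543 and 34080 in ileum, between 57.4% and 60.4% of the probes. No spot was saturated. Replicate spots of a probe gave an SD of a log2 difference between arrays of 0.056 to 0.0579 (median over probes). That spread covers spots of 1 hybridisation and not mice, pools or labelling, and the number of arrays limits the precision.

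The comparisons were DAO G181R minus wild-type within jejunum and within ileum, ileum minus jejunum within each genotype, and the difference of the 2 genotype differences. The following were fixed before the data were examined: the comparisons, 43 gene lists with 757 genes, the alternatives, and the rule for naming genes. The rule names Dao, the 10 highest and 10 lowest genes of each genotype comparison, the 10 genes of each direction most different in both tissues, the 10 of each direction most different between tissues in both genotypes, up to 4 members of each list that stood apart and up to 2 of other lists, 5 genes of each sign for the difference of differences, and the 5 largest bounds of each direction. Clone names and predicted models were passed over. Some list members that the rule allows are not reported here. The lists were 19 sets of cell type markers, 21 pathways, and 3 checks (circadian clock, immediate early and heat shock, sex-linked). The median log2 difference of each list with at least 5 measured genes was set among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below percentile 2.5 or above percentile 97.5. Lists of genes drawn at random would fall there in 5% of cases. Genes within a list are not independent, so these percentiles describe the arrays and are not p-values.

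The counting was tested on simulated data with the technical noise of the spots alone, and the list percentiles on the measured differences. In both genotype comparisons, 100 of 100 genes altered 4-fold and 0 of 100 altered 1.5-fold were counted at the 2-fold threshold, with 0 unaltered genes counted, among 21220 genes in jejunum and 21470 in ileum. With spot noise so small beside both folds, these counts were settled in advance and check the steps alone. Of 200 random lists of 15 measured genes, 5.5% stood apart in jejunum and 6.5% in ileum. The limits give about 5% by construction. After 0.3 log2 was added to the measured differences of the listed genes, 96.5% stood apart as higher in jejunum and 80.0% in ileum.

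The alternatives were quantile normalization, normexp background correction with an offset of 50, scaling on the median of detected probes, 3 other filters on dim probes, the mean of all probes of a gene, the deposited value table, random lists without matching, thresholds of 1.5-fold and 4-fold, and windows of 5 Mb and 20 Mb around Dao. One more, the deposited table without its filled probes, was chosen after seeing the data. The mean of all probes takes in each probe of a gene that was well above background on at least 1 of the 4 arrays. It can thus hold a probe at background on an array of the comparison. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for quantile normalization and normexp. Control probes were left out. No file was left unused.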

Results

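Gene expression was measured in the epithelial tissue of jejunum and ileum from mice with the wild-type or the G181R form of DAO, an enzyme that oxidises D-amino acids. The G181R allele is known as one that abolishes most of the enzyme's activity. All mice lacked T cell receptor beta and delta chains and therefore had no T cells with a receptor. Each of the 4 groups (jejunum wild-type, jejunum G181R, ileum wild-type, ileum G181R) was 1 array of RNA pooled from 5 mice. None of the values below has a replicate, and the only error at hand is that between replicate spots, an SD of 0.056 to 0.0579 for a log2 difference. The arrays showed 21648 and 22664 genes well above background in jejunum (wild-type and G181R) and 22176 and 22518 in ileum.

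Dao itself was nearly alike in the 2 genotypes and much lower in ileum than in jejunum. Its brightest probe, on chromosome 5 at 114475410 to 114475469 (mm9), had a processed signal of 1308.6 in wild-type and 1239.1 in G181R jejunum, a log2 difference of -0.11. In ileum its signals were 156.9 and 144.5, a log2 difference of -0.04. Dao was 9.88-fold lower in ileum than in jejunum in wild-type mice and 9.40-fold lower in G181R mice. A dimmer probe for Dao gave genotype differences of 0.43 in jejunum and 0.67 in ileum. G181R is a change of 1 amino acid, so the amount of Dao mRNA neither checks nor contradicts the genotype labels.

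The first comparison asks which genes of the jejunum differed between the DAO genotypes. In G181R jejunum, the cell cycle and Paneth cell lists were higher, and the B cell, type I interferon and xenobiotic metabolism lists were lower. The highest gene was B3galt5, a galactosyltransferase that builds glycan chains, at 17.3-fold (log2 4.11, chromosome 16 at 96541339 to 96541398). Saa2, an acute-phase apolipoprotein made by epithelium, was higher by 3.90 on the log2 scale. Duox2 and its maturation factor Duoxa2, which together make hydrogen peroxide at the epithelial surface, were 5.04-fold and 5.81-fold higher (log2 2.33 and 2.54). With normexp background correction, which pulls dim signals together, Saa2 stood at 2.49, Duox2 at 1.17 and Duoxa2 at 1.87. The lowest gene was Pck1, the enzyme that commits carbon to gluconeogenesis, 5.75-fold lower (log2 -2.52).

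Among the other highest genes in G181R jejunum were the secreted phospholipase Pla2g5 (log2 2.96), the small GTPase Rasd1 (2.84), Acacb, an acetyl-CoA carboxylase that restrains fatty acid oxidation (2.79), the cadherin Celsr3 (2.52), mesothelin Msln (2.31) and the serine protease Prss27 (2.21). Among the lowest were the exchanger Slc9b1 (-2.42), the water channel Aqp8 (-2.08), the actin-capping protein Tmod2 (-2.03), Pdk4, the kinase that shuts off pyruvate dehydrogenase in fasting (-2.02), Traf3ip3, Ms4a1, which encodes CD20 of B cells (-1.98, and -0.91 at its other probe), Ighd, the IgD heavy chain (-1.79), Hoxb13 (-1.78) and Lsmem1 (-1.77). Several of these rested on 1 probe among others: Acacb, Celsr3 and Tmod2 were below 2-fold (log2 0.96, 0.42 and -0.96) in the mean of their probes, and Slc9b1 and Traf3ip3 were at -1.03 and -1.34. For Celsr3 and Slc9b1 no other probe was well above background on both jejunum arrays, so their means take in signal at background. Of 21220 measured genes, 162 were at least 2-fold higher and 159 at least 2-fold lower, 1.51% together, and 18 and 9 were so at 4-fold. With normexp, 60 were higher and 34 lower, so the share higher was 63.8% in place of 50.5%, and Ms4a1, Ighd, Slc9b1, Tmod2, Traf3ip3, Hoxb13, Msln and Prss27 were then below 2-fold in jejunum, while Pla2g5 stood at 2.31, Acacb at 1.89, Rasd1 at 1.77 and Celsr3 at 1.69. Genes seen on 1 array only included H2bc22 (at least 9.50-fold higher), Adamts16 (at least 6.39-fold), Cpn2, Pirt and Insyn1, and on the other side Six3 (at least 7.81-fold lower), Pdcl2, Calcoco2, Myh7 and Fcmr, the Fc receptor for IgM (at least 5.08-fold lower). There were 34 named genes with a bound of at least 2-fold higher and 70 with a bound of at least 2-fold lower.

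Several immune gene lists were lower in G181R jejunum, and others did not stand apart. The B cell list had a median of -0.67 over 15 measured genes, below all 10000 random lists. Ms4a1, Ighd, the complement receptor Cr2 (-1.46) and Fcrla (-1.16) were lowest, and 5 of the 15 were at least 2-fold lower and 0 higher. Several members were dim in G181R jejunum, with signals of 9.7 for Ms4a1, 7.1 for Fcrla and 6.8 for Cxcr5. The lowest signal well above background on that array was 5.83. The brightest members, Cd37 and Ighm, differed by 0.14 and -0.46. With normexp, Ms4a1 stood at -0.52 and Ighd at -0.79. Genes of the T cell list, some of which innate lymphoid cells also express, had a median of -0.26, with all 13 measured genes lower (Cd8a -0.65, Cd4 -0.44). The innate lymphoid and NK cell list had a median of -0.36 (Il13 -0.72, Gata3 -0.48). The type I interferon list had a median of -0.38, with 23 of 24 genes lower, led by Ifit3 (-1.41), Rsad2 (-1.09) and Ifi44 (-0.88), which restrict virus growth. The interferon gamma list was at -0.14, with the guanylate-binding protein Gbp6 lowest (-1.21), and it no longer stood apart against random lists without expression matching. Plasma cell and IgA genes did not stand apart (median 0.11). Igha, the IgA heavy chain, differed by 0.15 and Jchain by 0.18; both were picked out after their values were seen. The macrophage and dendritic list (median -0.09), the inflammatory M1 list (0.06), the alternative M2 list (0.04), the IgA induction list (-0.11), the mast cell list (-0.03) and the M cell list (0.09) lay among the random lists. The MHC class II list (-0.14) lay just inside the limit, at percentile 2.79, with all 11 measured genes lower.

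The Paneth and cell cycle lists were among the 4 that stood apart as higher in G181R jejunum. The Paneth cell list, antimicrobial products of the crypt base, had a median of 0.46 with 15 of 17 genes higher, led by Defa21 (1.02), Pla2g2a (0.90), Mmp7 (0.68) and Wnt3 (0.66); alpha-defensins share near-identical sequence, so their probes can read each other. The cell cycle list had a median of 0.45 with 24 of 26 genes higher (Ccnb1 0.69, Mcm3 0.66, Cdk1 0.63). The unfolded protein and integrated stress response list had a median of 0.27 (Chac1 1.75, the asparagine synthetase Asns 1.34, Xbp1 0.58). The list of inducible epithelial antimicrobial genes had 7 of 20 members at least 2-fold higher, among them Saa2 and Duoxa2, but its median of 0.10 lay among the random lists. In the D-amino acid and serine list (median 0.14, also among the random lists) Psat1 and Phgdh, enzymes of serine synthesis, were higher by 1.47 and 1.04. The goblet cell list (0.05), the stem and crypt base list (0.06), the tight junction list (0.04), the cholesterol synthesis list (0.11), the NRF2 list (0.00), the amino acid absorption list (0.00) and the iron and copper list (-0.11) did not stand apart, although the mucin-branching enzyme Gcnt3 (1.91) and the glutathione peroxidase Gpx2 (1.60) were single high members.

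Several lists of enterocyte metabolism were lower in G181R jejunum. The xenobiotic metabolism list was at -0.48, with all 23 measured genes lower (Cyp2c55 -1.53, Ces1g -1.03, Cyp3a11 -0.96). The retinoid list was at -0.42 (Adh4 -1.57, Cyp26b1 -0.94, Rdh7 -0.74), the carbohydrate list at -0.23, with the gluconeogenic enzymes G6pc (-1.56) and Fbp1 (-1.03) lowest, the fatty acid oxidation list at -0.15 (Pdk4, Angptl4 -1.50), and the fat absorption list at -0.14 with 20 of 21 genes lower (Scarb1 -0.51, Apoa1 -0.40). The tuft cell list was at -0.18 (Sucnr1 -0.76), a call lost with no background filter and in the mean of all probes. The ileal bile acid and vitamin B12 list was at 0.17 (Slc51b 0.58, Fabp6 0.57), a call lost with normexp and without expression matching. Markers of other tissue moved as well, and so did the circadian clock check. The red cell list was at -0.49 (all 6 measured genes lower), the adipocyte list at -0.43 (Pck1, Cfd -1.07; lost with normexp), the fibroblast list at -0.23 (Lum -0.46) and the circadian clock list at -0.35 (Hlf -1.13, Cry2 -1.08). Pck1 was 18.1-fold lower in ileum than in jejunum in wild-type mice, while the adipocyte list median was 1.95 higher in ileum. Pck1 therefore need not mark adipocytes here. Smooth muscle (0.14), nerve and glia (0.16), endothelial (-0.09), exocrine pancreas (0.14), enteroendocrine (-0.08) and immediate early genes (-0.10) did not stand apart. In all, 19 of 42 lists stood apart, 4 higher and 15 lower, where lists drawn at random would give 2.1. Genes of a list are not independent, so this gap does not measure chance.

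The second comparison asks the same of the ileum. In G181R ileum, the medians of the interferon gamma, inducible antimicrobial and MHC class II lists were higher, while those of the xenobiotic metabolism and smooth muscle lists were lower. Lrg1, an acute-phase glycoprotein, was the highest gene at 72.1-fold (log2 6.17). Plet1, a surface protein of progenitor cells, was 29.0-fold higher, and Fut2, the fucosyltransferase that decorates the gut surface, 14.9-fold higher (log2 3.90). The lowest gene was Cyp2c55, a cytochrome P450, 22.2-fold lower (log2 -4.48). G6pc, the last enzyme of gluconeogenesis, and Angptl4, an inhibitor of lipoprotein lipase, were at -3.15 and -3.13. With normexp, Fut2, whose wild-type signal was 22.3, stood at 2.33, Plet1 at 4.205 in place of 4.86, Cyp2c55 at -3.73 and G6pc at -2.29.

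Other genes among the highest in G181R ileum were Trim10 (log2 3.63), Lypd3 (3.42), Tac1, which encodes substance P (3.19), B3galt5 (3.19), Ly6d (2.79), Socs1, a brake on cytokine signalling (2.79), and the GTPase Rhoj (2.71). Among the lowest were Cyp3a16 (-3.51), Cyp3a57 (-3.46), Cyp3a44 (-3.39), Cyp3a25 (-3.25), Cyp3a59 (-3.16) and the beta-defensin Defb37 (-3.19). The Cyp3a genes are related copies on chromosome 5, so their probes may read each other in part, which was not checked. They did not all read alike: in wild-type mice Cyp3a44 was 2.59-fold higher in ileum than in jejunum. Cyp3a16 was 22.7-fold lower there, and the other Cyp3a genes named were lower too. Lypd3 and Cyp3a16 lie among the filled probes of the deposited table, where both read -0.21; with normexp Lypd3 stood at 1.11, Trim10 at 1.69, Cyp3a16 at -1.52, Defb37 at -2.01, Cyp3a44 at -2.07, Cyp3a59 at -2.36 and Cyp3a57 at -2.87. Cdc73 ranked among the lowest by its brightest probe (-4.44), but its other probes differed by -0.02, and in the mean of its probes it was at -1.49. The share of measured genes at least 2-fold different was 5.22%, with 431 higher and 689 lower of 21470, and 70 and 86 at 4-fold. Genes seen on 1 array only included Cxcl5 (at least 26.6-fold higher), Cxcl1 (at least 17.3-fold) and S100a9 (at least 14.2-fold), all genes of neutrophil recruitment or of neutrophils, with Nlrp10 and Ccdc85a; on the other side were Defb40 (at least 19.1-fold lower), Defb39, Olfr1242, Casq2, a calcium store protein of muscle (at least 9.50-fold lower), and Cep85l. There were 63 named genes with a bound of at least 2-fold higher and 137 with one of at least 2-fold lower.

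Several immune gene lists were higher in G181R ileum. The interferon gamma list had a median of 0.96 with 11 of 22 genes at least 2-fold higher, among them Iigp1 (2.65) and Igtp (2.25), which attack pathogens inside cells, Nlrc5, the activator of MHC class I genes (2.28, and 1.56 in the mean of its probes), and the chemokine Cxcl9 (2.23). The type I interferon list was at 0.46, with 19 of 24 genes higher (Ifit2 1.65, Ifi44 1.61). The B cell list was at 0.72 with 16 of 18 genes higher (Cr2 0.93, Cxcr5 0.86, Fcmr 0.86). The MHC class II list was at 0.63 with 9 of 11 genes higher but 0 at least 2-fold higher (H2-Oa 0.97, H2-DMb1 0.74, Cd74 0.68). The inducible antimicrobial list was at 0.63 with 10 of 22 genes at least 2-fold higher (Retnlb 2.27, Saa3 1.99, Reg3a 1.84). In the same list 2 genes were at least 2-fold lower, with Reg4 lowest (-1.99). The M1 and M2 macrophage lists were at 0.63 and 0.59, led by Socs3 (2.24) and Pdcd1lg2 (1.15), and the macrophage and dendritic list at 0.28 (Ly6c2 2.26, Cd14 0.68). The plasma cell and IgA list was at 0.42 (Fkbp11 1.11, Ighg2c 0.89, Irf4 0.83). Igha differed by 0.31 and Jchain by 0.22; both were again picked out after their values were seen. The IgA induction list was at 0.33 (Nos2 1.63, Cxcl13 1.03), a call lost with normexp, with no background filter and in the mean of all probes. The T cell (0.18), innate lymphoid and NK (0.04), M cell (0.11), stem (-0.03), goblet (-0.08), Paneth (0.08) and endothelial (-0.20) lists did not stand apart, and the mast cell list had fewer than 5 measured genes.

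Several metabolic and cell type lists were lower in G181R ileum. The xenobiotic list was at -1.16, with 11 of 21 genes at least 2-fold lower (Abcb1a -2.02, Cyp2d26 -1.82). The retinoid list was at -0.46 (Cyp26b1 -2.59, Rdh7 -2.56, Lrat -1.46), the fatty acid oxidation list at -0.45 (Pdk4 -2.63), the carbohydrate list at -0.38 (Fbp1 -1.69, Treh -0.96, Sis -0.91), the bile acid and vitamin B12 list at -0.26 (Cubn -2.62, Amn -0.69; lost without expression matching), and the fat absorption list at -0.20 (Plin2 -1.25, Apoa1 -0.98). The tight junction list was at -0.15 (Cldn4 -1.73, Cldn8 -1.50; lost with the deposited values and without expression matching). The tuft cell list was at -0.52 (Sucnr1 -1.73, Dclk1 -1.37), and the enteroendocrine list at -0.45 (Pax6 -2.10, Scg2 -0.91), with Tac1 as an exception. The cell cycle list was higher, at 0.56 with all 26 genes higher (Rrm2 0.76, Birc5 0.76), and the stress response list was at 0.48 (Chac1 2.06, Asns 1.47).

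Several marker lists of tissue beneath the epithelium were lower in G181R ileum. The adipocyte list among them includes Pck1 (-1.89), which need not mark adipocytes here. The smooth muscle list had a median of -2.44, with all 12 genes lower and 9 of them at least 2-fold lower (Synm -2.98, Synpo2 -2.81, Tpm2 -2.78, Myl9 -2.73). Acta2 differed by -0.19 at its brightest probe and by -2.42 and -2.71 at other probes. The fibroblast list was at -0.55 (Lum -1.13), the adipocyte list at -1.04 (Car3 -1.15, Adipoq -1.09), the red cell list at -0.63 (Hbb-b1 -0.87), and the nerve and glia list at -0.36 (Stmn2 -2.01, Uchl1 -1.41; lost with normexp and in the upper range of expression). The circadian clock list was at -0.57 with all 15 genes lower (Cry2 -1.86, Tef -1.52), and the immediate early list at -0.17 (Fosb -1.14; lost with the deposited values, with or without their filled probes, and without expression matching). The D-amino acid and serine list (0.11; Psat1 1.20, Shmt2 1.02), amino acid absorption (-0.07), iron and copper (-0.02), cholesterol synthesis (-0.04), NRF2 (-0.03) and exocrine pancreas lists (-0.18) did not stand apart. In all, 28 of 41 lists stood apart, 12 higher and 16 lower, where lists drawn at random would give 2.05, with the same limit as in jejunum.

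**Figure D1:**
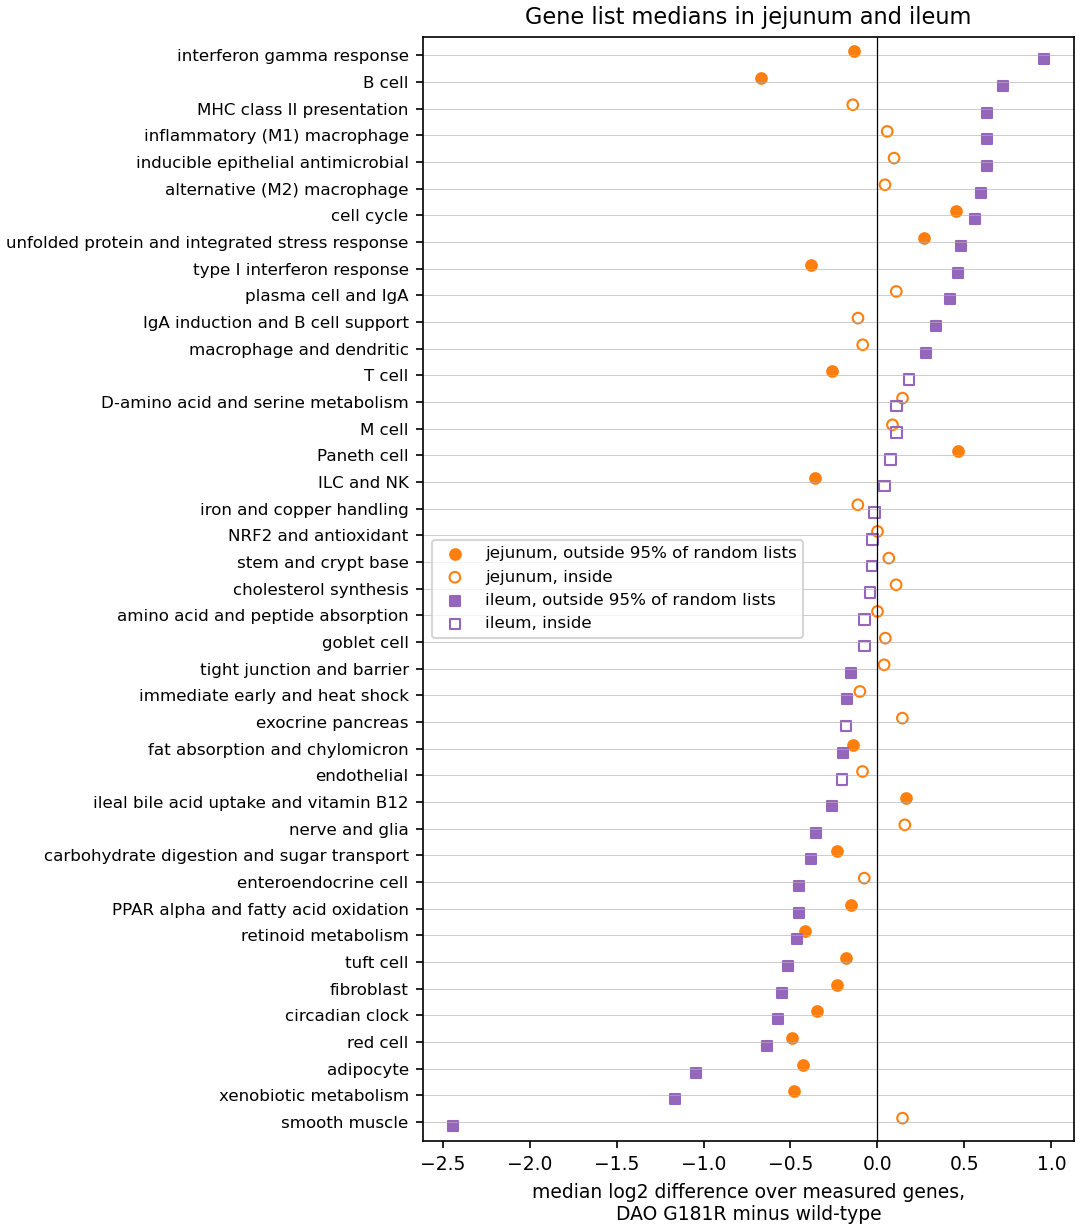
Median log2 difference, DAO G181R minus wild-type, over the measured genes of each of 41 gene lists (lines), in jejunum (orange circles) and ileum (purple squares); filled marks lie outside 95% of random expression-matched lists. The B cell list lay at -0.67 in jejunum and 0.72 in ileum, and smooth muscle at -2.44 in ileum.

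The next comparison asks which genotype differences the 2 tissues shared. In G181R tissue of both kinds the cell cycle and stress response lists were higher, and the xenobiotic, retinoid, carbohydrate and fatty acid oxidation lists lower. The fat absorption, tuft cell, fibroblast, red cell, adipocyte and circadian clock lists were lower in both as well. B3galt5 was higher by 4.11 in jejunum and 3.19 in ileum on the log2 scale, and Socs3, a brake on cytokine signals through STAT3, by 1.78 in jejunum and 2.24 in ileum. Retnlb, a goblet cell antimicrobial protein, was higher by 1.77 and 2.27. Lower in G181R were Pdk4 (-2.02 in jejunum and -2.63 in ileum), Pck1 (-2.52 and -1.89), G6pc (-1.56 and -3.15) and Angptl4 (-1.50 and -3.13).

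The other genes most higher in both tissues were Celsr3, Prss27, the neighbouring genes Gml and Gml2 (2.15 in jejunum and 2.33 in ileum for Gml), the sulfotransferase Chst4 (1.84 and 2.64), Zbtb4 (1.84 and 2.13) and Mup2 (1.76 and 2.17), one of a family of near-identical urinary protein genes. The others most lower in both were Anp32a (-1.67 and -2.28), the transporter Slc17a4 (-1.64 and -1.72), Cyp2c55, the alcohol dehydrogenase Adh4, the laminin chain Lama3 (-1.29 and -2.51) and Armc2 (-1.25 and -2.51). The second probe of Zbtb4 gave -0.06 and -0.67 and that of Anp32a -0.17 and -0.57, so neither gene reached 2-fold at both of its probes. In the mean of its probes Armc2 was at -0.91 in jejunum and Celsr3 at 2.03 in ileum, though neither had another probe well above background on both arrays. With normexp, Retnlb, Mup2, Prss27 and Armc2 were below 2-fold in jejunum and Adh4 in ileum, while Chst4 stood at 1.07 and 1.89, Gml2 in jejunum at 1.475 in place of 2.105, and Pdk4 and Armc2 in ileum at -1.90 and -1.19; in the deposited table the filled probe of Prss27 read -0.19 and -0.21. Across 20413 genes measured on all 4 arrays, the differences in jejunum and ileum correlated with Pearson's r 0.487 and Spearman's rho 0.494; these are across genes, which are not independent replicates. There were 87 genes at least 2-fold higher in both tissues, where independence would give 2.85, and 40 lower in both, where it would give 3.48. The labels do not say whether the same mice gave both tissues. With no background filter the correlation was 0.175.

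**Figure D2:**
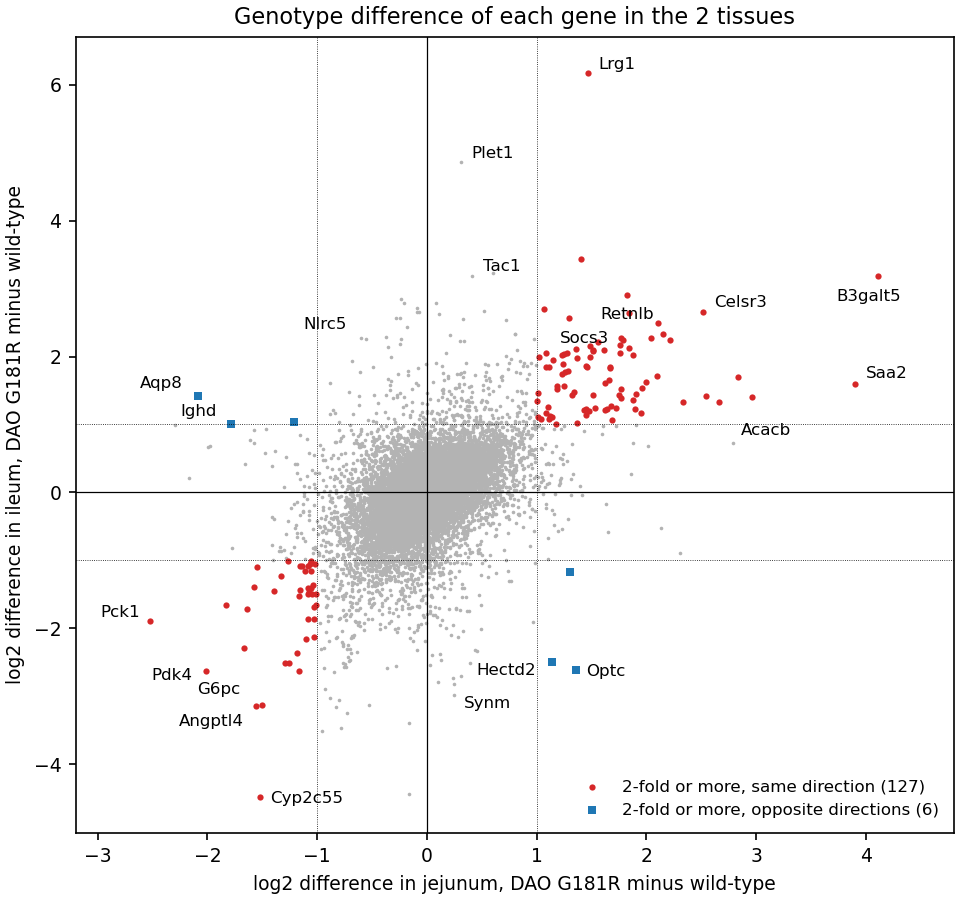
Log2 difference, DAO G181R minus wild-type, in jejunum (horizontal) and ileum (vertical) for 20413 genes measured on all 4 arrays (points); dotted lines mark 2-fold. The 127 genes at least 2-fold different in the same direction are red circles, and the 6 in opposite directions are blue squares.

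Some genes differed between genotypes by unlike amounts in the 2 tissues; this contrast was not tested, as 1 array per group leaves nothing to test it with. The difference of differences (ileum minus jejunum) was largest upward for Lrg1, which was higher by 1.47 in jejunum and 6.17 in ileum, Plet1 (0.31 and 4.86), Aqp8 (-2.08 and 1.41), Ly6d (-0.21 and 2.79) and Nlrc5 (-0.60 and 2.28). It was largest downward for Cdc73, again by 1 probe of several, Optc (1.36 and -2.61), Hectd2 (1.14 and -2.50), Cyp3a44 and Synm, an intermediate filament protein of muscle (0.24 and -2.98). With normexp, values below 2-fold were those of Aqp8 in ileum (0.43), Hectd2 in jejunum and ileum (0.59 and -0.67), and Optc and Lrg1 in jejunum (0.54 and 0.47), while Optc and Synm in ileum stood at -1.09 and -1.925. In the mean of their probes Hectd2 was at 0.60 in jejunum and -1.64 in ileum, and Nlrc5 at 1.56 in ileum. Nlrc5 had no other probe well above background on both ileum arrays. The difference of differences reached 2-fold for 357 genes upward and 422 downward of 20413. Of the gene lists, 2 were higher in both tissues (cell cycle, stress response), 10 were lower in both, and 4 stood apart in opposite directions. Of the latter, the interferon gamma list in jejunum and the bile acid and vitamin B12 list in both tissues lost their calls without expression matching, and the bile acid list in jejunum also with normexp.

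Because the allele was bred into its strain, genes near Dao were counted apart. Within 10 Mb of Dao on chromosome 5, 11 of 310 genes were at least 2-fold different in jejunum (3.55%, 95% Wilson interval 1.99% to 6.24%), against 1.48% of genes elsewhere. In ileum the count was 21 of 308 (6.82%, 4.50% to 10.2%), against 5.19% elsewhere. These intervals treat neighbouring genes as independent. The other planned measure, the median absolute log2 difference of genes in the window, lay among random expression-matched lists in both tissues. It was 0.187 in jejunum (random lists 0.143 to 0.191) and 0.246 in ileum (0.20 to 0.268). In both tissues and in the same direction, 6 of 296 genes in the window were at least 2-fold different (2.03%, 0.93% to 4.35%), against 0.60% elsewhere, a count made after the results were seen. Spp1, which encodes osteopontin, Rpap2 and the replication factor Rfc5 were among these (1.62, -1.05 and 1.95 in jejunum); they were picked out after their values were seen. Acacb, among the highest genes of jejunum, also lies in this window, with its brightest probe at 114700702 to 114700761. Its 3 probes ran from -0.25 to 2.79 in jejunum and from 0.12 to 0.73 in ileum. Its place beside Dao was picked out after the values were seen. With no background filter the ratio of shares in jejunum was 1.15 in place of 2.39.

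The last comparison asks how ileum differed from jejunum within each genotype. Ileum was marked by bile acid transport and jejunum by lactose digestion, drug metabolism and fat absorption. Fabp6, the ileal bile acid carrier, was higher in ileum by 13.72 on the log2 scale in wild-type and 13.09 in G181R mice, and Slc10a2, the bile acid importer, was 371-fold and 256-fold higher (log2 8.535 in wild-type mice). With normexp the log2 differences were 11.07 and 10.91 for Fabp6, whose jejunal signals of 11.2 and 17.0 lay near the lowest seen well above background, and 7.39 and 6.93 for Slc10a2. Lct, the lactase gene, stood at -9.83 and -8.73, and Cyp2b10, a drug-metabolising P450, at -8.23 and -8.40; with normexp Lct stood at -8.96 and -8.11, and Cyp2b10 in G181R mice at -7.81. Genes seen in 1 tissue only included the posterior homeobox gene Hoxb9 (at least 172-fold higher in wild-type and at least 152-fold in G181R ileum) and Tmprss15, which encodes enteropeptidase (at least 481-fold and at least 422-fold lower).

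Other genes most higher in ileum in both genotypes were Saa2, Saa1 (7.67 and 7.29), Cryab (7.50 and 7.05), Krtap19-1, Krtap4-8, Gp1bb, Mal (5.78 and 7.25) and Tmigd1. The others most lower were Reg1 (-9.08 and -8.90), Cyp2b9, the transcription factor Onecut2 (-8.00 and -7.66), Adh4, Ugt2a3, Enpp3, the antimicrobial peptide Leap2 (-6.17 and -7.39) and the lactate transporter Slc5a12. Gp1bb and Tmigd1 read lower in ileum in the deposited table (-0.83 in wild-type, -0.86 in G181R), where their probes hold the fill value. The place of Gp1bb rests on 1 of 2 probes (6.62 in wild-type and 6.14 in G181R, against 1.57 and 1.27 at the other), and in the mean of their probes Gp1bb was at 4.095 and 3.70 and Enpp3 at -5.35 and -5.59 in place of -6.65 and -7.025. With normexp several of these differences were nearer to 0 by over 1.5-fold, most of all that of Adh4 (-7.03 to -3.85 in G181R mice). In wild-type mice 1533 genes were at least 2-fold higher and 1891 lower of 20745, and in G181R mice 1565 and 1874 of 21469. The tissue difference correlated between genotypes with Pearson's r 0.886 and Spearman's rho 0.835 across genes; 1024 genes were higher and 1300 lower in both, and 17 went in opposite directions.

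Lists that stood apart in both genotypes included cholesterol synthesis (medians 1.34 in wild-type and 1.28 in G181R), cell cycle (1.13 and 1.20), Paneth cell (1.94 and 1.62), goblet cell (1.12 and 0.78), M cell (0.48 and 0.72) and B cell genes (1.43 and 2.71), all higher in ileum. Fat absorption (-1.47 and -1.83; Fabp1 -5.26 and -5.82), carbohydrate (-1.87 and -2.21), xenobiotic (-2.04 and -2.36), retinoid (-1.22 and -1.35) and endothelial genes (-1.13 and -0.85) were lower. The type I interferon list was lower in ileum, at -2.14 in wild-type and -1.21 in G181R mice (Usp18 -3.73 and -2.03), and so was the interferon gamma list, at -1.21 and -0.35; in G181R mice the latter no longer stood apart with the deposited values or the mean of all probes. The smooth muscle list was higher in ileum in wild-type mice, at 1.45, and lower in G181R mice, at -1.05 (Cnn1 1.90 and -0.59). In all, 30 of 41 lists stood apart in wild-type and 32 of 41 in G181R mice.

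**Figure D3:**
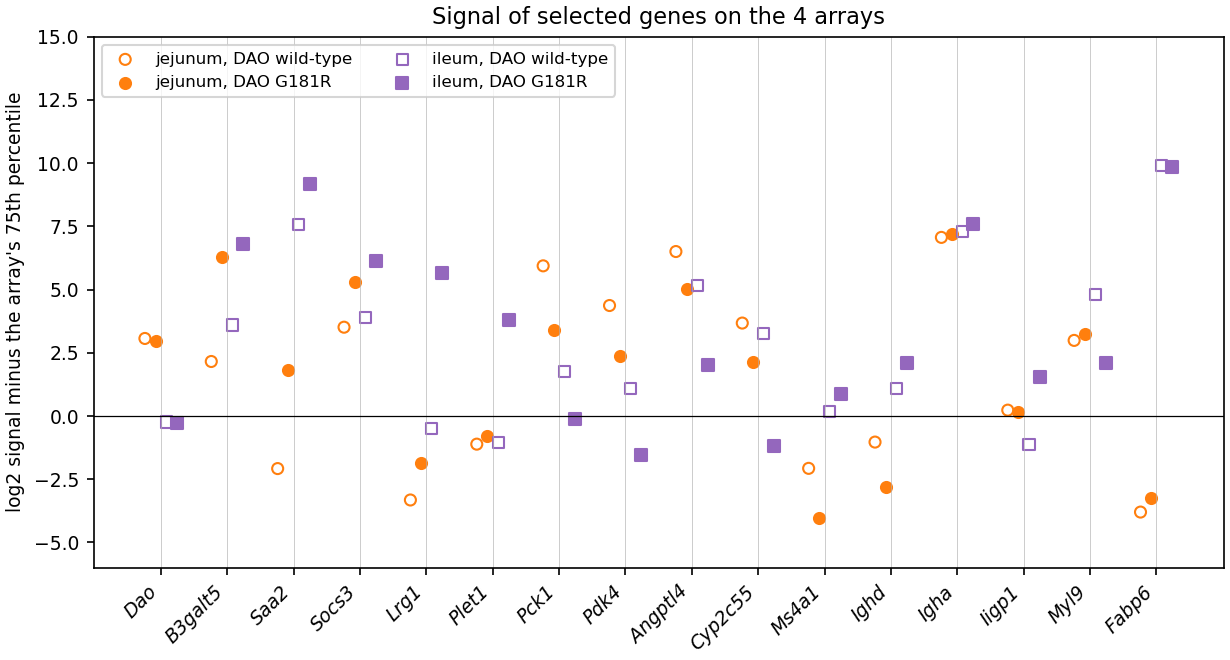
Log2 processed signal minus the array's 75th percentile for 16 genes on the 4 arrays: jejunum (orange circles) and ileum (purple squares), wild-type (open) and DAO G181R (filled). Dao lay lower in ileum than in jejunum and nearly alike in the genotypes, while Lrg1 was 72.1-fold higher in G181R ileum.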

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

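Every test of the B cell and smooth muscle patterns was chosen only after those results were seen; so were the counts, near Dao and by tile of the genome, of genes that differed in both tissues, while the other tests of the neighbourhood of Dao and those of sex and time of day were set beforehand. The B cell result and those of the last paragraph stood out because the genotype difference went one way in jejunum and the opposite way in ileum; smooth muscle and the genotype differences as a whole did not meet that rule and were weighed besides. With 1 array per group no contrast between the tissues was tested.

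The B cell list differed by 1.39 more in ileum than in jejunum (medians -0.67 and 0.72), and Ighd by 2.79 (in jejunum -1.79, with normexp -0.79). A different share of all non-epithelial cells in the scraped ileum is argued against. The B cell median exceeded the fibroblast median there by 1.27 (95% bootstrap interval over genes 0.98 to 1.47), while such a share would move both alike. The interval does not cover pools, and the test covers ileum alone. In jejunum the fibroblast (-0.23), red cell (-0.49), T cell (-0.26) and innate lymphoid and NK (-0.36) lists were lower too. Smooth muscle, nerve and glia and endothelial lists did not stand apart there, so such a share stays open in jejunum. A different amount of lymphoid follicle in the scraped pieces may account for the B cell pattern and cannot be told apart from the genotype: the M cell list, epithelium that covers follicles, was at 0.086 in jejunum (-0.20 to 0.26) and 0.11 in ileum, too wide to decide. The brightest listed gene, Cd37, hardly differed (0.14 and 0.05), the next, Ighm, had signals of 684.5 and 509.2 in jejunum and 1735.5 and 2402.9 in ileum (wild-type, then G181R), and 1 of the 20 listed genes also stands in another list. An effect of DAO on B cells stays open and untested.

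Smooth muscle genes were lower in G181R ileum at a median of -2.44 and not apart in jejunum (0.14). The median was -2.42 under the other scaling nearest to 0 and -2.46 under the remaining one, both below the random lists. Scaling on detected probes moves all genes of an array alike, so it could not bring the list among the random lists. Quantile normalization moves genes of like signal alike, and the random lists were matched on expression, which left it little room to do so. The values therefore hold under other scalings but were largely settled in advance. Less muscle layer in the scraped ileum of the G181R pool than of the wild-type pool is a candidate explanation: the nerve and glia list, cells that lie between muscle layers, was at -0.36, with an interval of -1.41 to 0.65 that leaves it open. Against jejunum, the smooth muscle list in ileum was at 1.45 in wild-type and -1.05 in G181R mice. Which of the 2 ileum pools departed from the usual cannot be told. The brightest muscle gene of wild-type ileum, Myl9, had signals of 5224.0 and 747.4 there (wild-type, then G181R), and Acta2 4529.1 and 3756.2 by its brightest probe and 2889.2 and 511.9 by another. Biological loss of muscle transcripts with the genotype was not tested and stays open.

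The genotype differences as a whole could come from the chromosome segment bred in with the allele, from the sex of the pooled mice, or from the time of day, beside DAO itself. The segment, whose length is unknown, cannot be told apart from DAO. The share of genes within 10 Mb of Dao at least 2-fold different was 1.31 times that elsewhere in ileum and 2.39 times in jejunum. In ileum the interval of the share includes the share elsewhere. Within 20 Mb the ratios were 1.06 in ileum and 1.68 in jejunum. The median absolute difference of genes within 10 Mb lay among the random lists in both tissues. For genes different the same way in both tissues the ratio within 10 Mb was 3.37. Among 133 tiles of 20 Mb, the highest share of such genes was 4.30%, against 2.03% in the 10 Mb window. That tile lay outside the window but also on chromosome 5, at neighbouring genes of the Ugt2b family. As the segment may be longer than the window, the tile speaks neither for nor against it. The 10 Mb window holds 11 of the 321 genes different in jejunum and 21 of the 1120 in ileum, and the 20 Mb window 11 and 24. A switch of sex between pools is argued against, since the largest genotype difference of 4 Y-linked genes was 0.33 and Xist was well above background on 0 of the 4 arrays. A mix differing by 1 mouse could move Y-linked genes by less than the set bound of 0.585, so they cannot exclude it. Against such a mix speaks Xist alone, and no array gave a signal to show that its probe works. Time of day stays open: the mean of Dbp, Per2, Per3, Nr1d1 and Nr1d2 minus that of Arntl, Clock and Npas2 (Ciart, also planned, was not measured in either tissue) differed by -0.34 in ileum (-0.73 to 0.05) and -0.19 in jejunum (-0.40 to 0.01), below the set bound of 0.58 in size, but the ileal interval reaches past it. The circadian clock list as a whole stood apart as lower in both tissues (-0.35 in jejunum and -0.57 in ileum). An effect of the G181R allele stays open and was not tested against cage, diet or litter.

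The type I interferon list differed by 0.85 more in ileum than in jejunum (medians -0.38 and 0.46). The interferon gamma list differed by 1.09 (medians -0.14 and 0.96), and in jejunum it stood apart only with expression matching. The ileal bile acid and vitamin B12 list differed by -0.43 (medians 0.17 and -0.26), calls lost without expression matching in both tissues and with normexp in jejunum. Aqp8, a water channel, differed by 3.50 (-2.08 in jejunum, 1.41 in ileum; with normexp 0.43 in ileum). Gbp6, an interferon-inducible GTPase, differed by 2.25 (-1.21 and 1.04). Hectd2, a ubiquitin ligase, differed by -3.64 (1.14 and -2.50; with normexp 0.59 and -0.67, in the mean of its probes 0.60 and -1.64). Optc, an extracellular matrix protein, differed by -3.97 (1.36 and -2.61; with normexp 0.54 and -1.09). Thsd7a, a membrane protein, differed by -2.47 (1.31 and -1.17).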

How the results depend on the processing

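The deposited table without its filled probes was chosen as an alternative after seeing the data; the other alternatives were set beforehand. No replicate could be left out, as each group has 1 array. The counts of lists that stood apart stayed within 18 to 24 (jejunum genotype), 25 to 28 (ileum genotype), 28 to 33 (tissue, wild-type) and 30 to 33 (tissue, G181R). Of 165 list medians under 10 alternatives, 0 calls reversed, 39 were lost and 37 gained. Where they stayed within 1.5 times the main count, the counts of genes at least 2-fold different lay between 254 and 381 (jejunum genotype), 944 and 1139 (ileum genotype), 3177 and 4936 (tissue, wild-type) and 3169 and 4906 (tissue, G181R); the highest tissue counts, 4936 and 4906, came from requiring 1 array above background.

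With normexp the counts, in the same order, were 94, 395, 1791 and 1735, the genotype correlation was 0.585 and the difference of differences reached 2-fold for 224 genes; its offset of 50 shrinks differences of dim genes. It moved 67 of 121 named differences by over 1.5-fold and took 17 of them below 2-fold. Requiring 1 array above background gave genotype counts of 1006 and 2002, a genotype correlation of 0.387 and a difference of differences of at least 2-fold for 1312 genes. With no background filter the counts were 2811, 3508, 6976 and 6862, the correlations 0.175 (genotype) and 0.667 (tissue), the difference of differences 4998 and the ratio around Dao in jejunum 1.15; these 2 filters admit more, dimmer genes. The last also moved the median of all genes to -0.12 (ileum genotype) and -0.27 (tissue, wild-type). The 1.5-fold threshold gave 1587, 3318, 7431 and 7460 genes and the 4-fold threshold 27, 156, 809 and 831, by construction.

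In the deposited value table, Gp1bb and Tmigd1 reversed to -0.86 (tissue, G181R) and -0.83 (tissue, wild-type), Lypd3 to -0.21 (ileum genotype), and Prss27 to -0.21 in ileum and -0.19 in jejunum. These are the differences between the single fill values of the arrays, and without the filled probes 0 of 117 named differences were below 2-fold. In the mean of all probes 8 of 121 were. The lowest signals well above background, 5.83 to 7.36, limit what could be seen in dim genes.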

Other observations

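The observations below were all chosen after the results were seen, apart from the gene lists; they are values with no explanation offered.

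Il22, a cytokine of innate lymphoid cells that drives epithelial defence, was well above background on the 2 G181R arrays and on neither wild-type array. Its brighter probe in ileum had signals of 5.5 in wild-type and 121.3 in G181R, and in jejunum 2.5 and 7.9. A second probe had 7.3 and 36.9 in ileum and 6.0 and 9.0 in jejunum. The lowest signal well above background was 5.83 on the G181R and 7.36 on the wild-type jejunum array. The call for Il22 in jejunum thus rests on dim signals and unequal limits. Of the Reg family, Reg3b stood at 0.02 in jejunum and 0.15 in ileum, Reg3g at 0.12 and 0.13, and Reg4 at -1.99 in ileum (log2 difference, G181R minus wild-type).

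Claudins, which set the permeability of tight junctions, went different ways: Cldn2 was at 1.14 in jejunum and -0.25 in ileum, and Cldn4 at -0.63 and -1.73. Of the clock genes, members of both arms were lower in G181R ileum, with Arntl at -0.56 and Npas2 at -0.48 beside Nr1d1 at -1.19 and Per2 at -1.20. Transporters of amino acids held single large values, with Slc6a20a at -0.85 and -1.59, Slc7a8 at -0.35 and -1.15, and Slc6a14 at 1.86 in ileum.

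In the deposited value table, 2356 probes hold a single value per array: 5.733 and 5.545 in jejunum (wild-type and G181R), 4.898 and 4.686 in ileum. Each of the 4 columns has them at the same probes, which are all the probes among the first 2537 features. In that table Dao therefore reads as lower in ileum by -0.83 in wild-type and -0.86 in G181R, where its scanner signals gave -3.30 and -3.23.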
